A study of Mus musculus with 2 samples.

How the data were processed

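RNA expression was measured in regenerating tibialis anterior muscle of adult mice of mixed 129Sv and C57BL6 background, 7 days after 50 µl of 10 µM cardiotoxin had been injected into the right leg muscle. Cardiotoxin is a snake venom peptide that destroys muscle fibres and leaves satellite cells able to rebuild them. Per the labels' protocols, total RNA was extracted with Trizol from 5 wild type and 5 Mef2a knockout muscles, pooled in equimolar amounts within each genotype, and hybridised as biotin-labelled target to 1 array per genotype. The mice were 2 to 4 months old and of both sexes, per the labels. There are thus 2 arrays and no replicates. Pooling averages over mice, and neither the spread between mice nor that between arrays can be estimated from the data.

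The deposited table holds 1 value per probe set and array. The values are log2 expression values that the authors obtained with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, normalizes between arrays by quantiles and summarises the probes of a probe set. Program versions and settings are not given in the sources used here. The values were used as deposited. After sorting, the values of the 2 arrays differ by at most 0.139, so that a change in total RNA content, or one shared by most genes, cannot be seen in them. No detection calls and no probe-level values were used here, and the precision is limited by the number of arrays.

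Of 35557 probe sets, 21789 were annotated to 1 gene symbol, 1621 to several and 12147 to none in the platform annotation used here. For 21698 of those with 1 symbol the gene identifier was found in the RefSeq gene table of GRCm38.p6, and no symbol needed an update. Probe sets with several symbols or none were left out of the gene comparison. Where a gene had more than 1 probe set, as 999 genes did, the one with the highest mean was used. This gave 19938 genes. A gene was treated as measurable when the higher of its 2 values reached a floor of 4.40 log2 units, the median of all values of the table. The floor left 11787 genes. It is an arbitrary limit: 95% of the 1027 olfactory receptor genes, which muscle is not expected to use, lay below 3.68.

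Differences are log2 values of the labelled knockout pool minus the wild type pool, computed in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. Without replicates no test and no p-value is given. Genes were counted past fixed limits of 1.5-fold and 2-fold. To show how far a gene stood from the scatter of the arrays, the size of its difference was ranked among the 500 genes of nearest mean expression. The robust SD of the difference (from the median absolute deviation) was 0.28 over the genes at or above the floor. RMA values near the floor understate true differences.

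A total of 37 gene lists (pathways, structures and cell type markers) were fixed before the data were examined. Each list of at least 5 measured genes was described by its median difference and by the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean expression to match its members. A list was said to stand apart below percentile 2.5 or above 97.5. These percentiles describe the 2 arrays only, since genes of a list are regulated together and are not replicates. With 36 such lists, a few would stand apart by chance even if genes varied independently. The random lists were drawn gene by gene, and genes regulated together can make more lists stand apart by chance. How many more cannot be told from 2 arrays. Lists overlap, so their counts are not additive.

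Genes named in the text follow a rule also fixed beforehand: the Mef2 genes, the 12 largest and 12 smallest differences among measurable genes past 2-fold (leaving out predicted genes, receptor families of smell and immune receptor segments), and up to 3 members per list with the largest differences at or above the floor. Other genes are named as chosen after their values were seen. The counting and the list percentiles were tested on simulated data with 200 changed genes among 19938, all 200 with a mean at or above the floor. The scatter was drawn as normal and independent between genes, with the robust SD of the real difference at like expression. Of genes changed by 1.5 and 2.0 log2 units, 93.0% and 100% were called, with 4 unchanged genes. Real scatter with heavier tails would give more such calls, so the 4 do not estimate the false calls among the real genes. Of simulated unchanged 25-gene lists, 3.5% stood apart, against 88.0% of those shifted by 0.2. These lists held randomly drawn genes with independent scatter and a mean at or above the floor. The 3.5% therefore does not estimate how often real lists, whose genes are regulated together, stand apart by chance.

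Alternatives tried were median-centred differences, removal of a loess trend on mean expression (statsmodels 0.14.6, span 0.3), the mean of all probe sets of a gene, other floors and fold limits, inclusion of probe sets with several symbols, and, for lists, their mean, their members at or above the floor, omission of the member farthest from 0 and random lists not matched on expression.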

Results

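Expression was profiled in 2 pools of regenerating mouse tibialis anterior muscle, 1 of wild type and 1 of Mef2a knockout animals, each made of RNA from 5 mice taken 7 days after cardiotoxin injury. MEF2A is a transcription factor of the MEF2 family that drives muscle genes. The comparison asks which genes differ in regenerating muscle when it is absent. Each pool was measured on 1 array, so every value below rests on 1 measurement per genotype and has no replicate error. Values are log2 RMA values and ran from 0.14 to 13.08 in the wild type pool and from 0.13 to 13.17 in the labelled knockout pool. Across 19938 genes the pools correlated with a Pearson r of 0.988, genes not being independent replicates.

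The Mef2a transcript itself was not lower in the labelled knockout pool. Its only probe set read 8.92 in the wild type pool and 9.06 in the labelled knockout pool, a difference of 0.14 that was smaller in size than those of most genes of like expression (percentile 34.0 of 500). Mef2c read 9.88 and 9.80, and Mef2d 7.90 and 7.86, in the same order. Mef2b shares its probe set with other genes and was left out. The labels do not say which part of Mef2a is deleted, nor do the files place the probes along the transcript. A probe set outside the deleted part need not read lower, so Mef2a does not check the genotype labels here, and the direction of each difference below rests on the labels alone.

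More genes were higher than lower in the labelled knockout pool. Of 11787 measurable genes, 200 (1.70%) were at least 2-fold higher and 22 (0.187%) at least 2-fold lower. At 1.5-fold the numbers were 760 and 224. At 3-fold, 40 genes were higher and 0 lower. The count of lower genes past 2-fold depended on the floor, with 43 under no floor and 10 with the floor at the 75th percentile of all values.

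**Figure D1:**
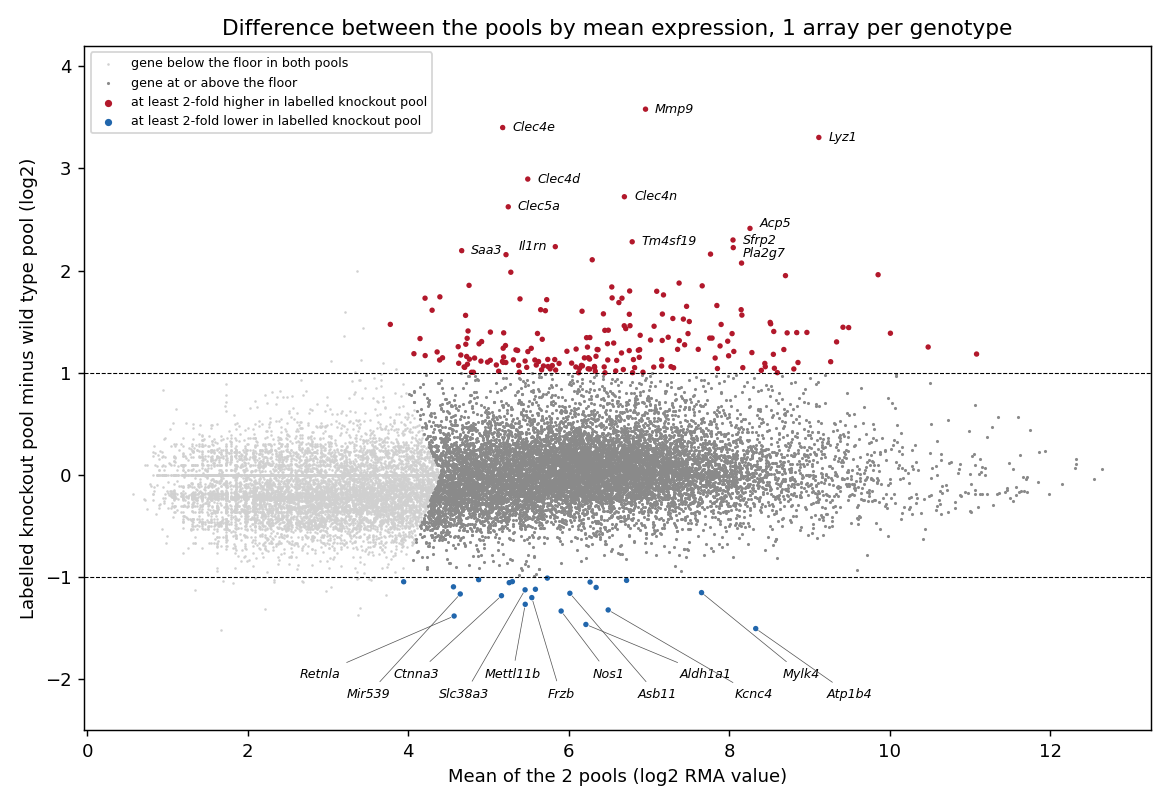
Each point is 1 gene, with the mean of the 2 pools (log2 RMA value) on the x axis and the log2 difference, labelled knockout pool minus wild type pool, on the y axis. Dashed lines mark 2-fold, and the 200 red points above them outnumber the 22 blue points below. The 12 largest and 12 smallest differences among named genes are labelled.

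Among the 12 genes with the largest differences were a matrix protease, 4 C-type lectin receptors, a lysozyme and a secreted WNT antagonist. Mmp9, a gelatinase secreted by inflammatory cells, was higher by 3.58 on the log2 scale in the labelled knockout pool (8.75 against 5.16 in the wild type pool). The C-type lectin receptors Clec4e, Clec4d, Clec4n and Clec5a, which macrophages and other myeloid cells use to sense damage and microbes, were higher by 10.6-fold, 7.45-fold, 6.60-fold and 6.17-fold. Lyz1, a lysozyme gene, was 9.88-fold higher, but its near-identical copy Lyz2 (2.27-fold higher) may share its signal, so the value is uncertain. Acp5, the tartrate-resistant acid phosphatase of osteoclasts and some macrophages, was 5.33-fold higher. Sfrp2, which binds WNT proteins, was 4.92-fold higher (9.20 against 6.90). Tm4sf19 was 4.87-fold, Il1rn, the interleukin 1 receptor antagonist, 4.71-fold, Pla2g7, a lipoprotein-associated phospholipase, 4.68-fold and Saa3, an acute phase protein, 4.58-fold higher. Each of these 12 exceeded at least 99.4% of the 500 genes of nearest mean expression. Since they were picked for the size of their differences, such a rank follows from the choice and is no added support. The wild type values of Clec4e (3.48), Clec4d (4.04), Clec5a (3.93) and Saa3 (3.57) lay below the floor, so their folds are poorly bounded.

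The 12 lowest genes included ion transport, enzyme and signalling genes of several kinds. Atp1b4, a muscle member of the Na,K-ATPase beta subunit family, was 2.84-fold lower (7.58 against 9.08). Nos1, the neuronal nitric oxide synthase of the fibre membrane, was 2.52-fold lower, and Kcnc4, a voltage-gated potassium channel, differed by -1.32 on the log2 scale. Asb11, an adaptor of a ubiquitin ligase, was 2.23-fold lower and Mylk4, a kinase of the myosin light chain kinase family, 2.22-fold lower. Aldh1a1, which makes retinoic acid, was 2.76-fold lower, Mettl11b 2.41-fold, Frzb, another secreted WNT antagonist, 2.30-fold, Ctnna3, an alpha catenin, 2.27-fold, and Slc38a3, a glutamine transporter, 2.18-fold lower. Retnla, a secreted protein of alternatively activated macrophages, was 2.61-fold lower, to a value of 3.88 below the floor. Mir539, a microRNA gene of the Dlk1-Dio3 locus, was 2.24-fold lower, to 4.06, also below the floor. Each of these 12 exceeded at least 98.6% of the genes of nearest mean expression, a rank that again follows from how they were picked.

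Markers of macrophages and monocytes were higher as a group. Of 31 measurable members, 27 were at least 1.5-fold higher, 19 of these at least 2-fold, and none was 1.5-fold lower. The median of all 34 measured members was 1.09 on the log2 scale, a 2.13-fold difference, and lay above all 10000 matched random lists, whose central 95% ran from -0.08 to 0.14. Msr1, a scavenger receptor, was 4.31-fold and Gpnmb, a glycoprotein of lipid-laden macrophages, 3.89-fold higher. Among members chosen after their values were seen, Cd68 was higher by 1.45, Adgre1 by 0.90, Csf1r by 0.80 and C1qa by 0.97 on the log2 scale, while Fcgr1 (0.04), Cx3cr1 (0.22) and Arg1 (-0.10, below the floor) differed by less than 1.5-fold.

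Other immune lists differed by less. Chemokines and cytokines had a median of 0.37 (percentile 100), with 11 of 23 measurable members at least 1.5-fold higher and none lower, among them Ccl3 (2.64-fold, from 4.32 below the floor), Csf1, the macrophage growth factor (2.54-fold), and Ccl7 (2.02-fold). Antigen presentation and dendritic cell genes had a median of 0.22 (percentile 99.4), with Itgax, an integrin chain of myeloid cells, 2.89-fold, and Cd74 1.62-fold higher, and Cd86 1.56-fold higher from a wild type value of 3.84 below the floor. The neutrophil list stood apart (median 0.28, mean 0.46, percentile 100, median 0.42 with the loess trend removed and 0.94 over members at the floor), yet only 3 of its 15 members reached the floor: Mmp9, Lcn2 (1.93-fold higher) and Csf3r (0.38 on the log2 scale). Lymphocyte genes were near background, with 1 of 21 measured members at the floor (Thy1, also a fibroblast gene, at 0.62, or 0.55 with the loess trend removed), a median of 0.00 and a mean of -0.03. They did not stand apart, though they did with the loess trend removed (percentile 98.1). Interferon-stimulated genes went the other way. Their median was -0.22 (percentile 0.02), and 3 of 23 were at least 1.5-fold lower: Rsad2 (1.84-fold), Iigp1 (1.63-fold) and Ifit3 (1.57-fold).

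**Figure D2:**
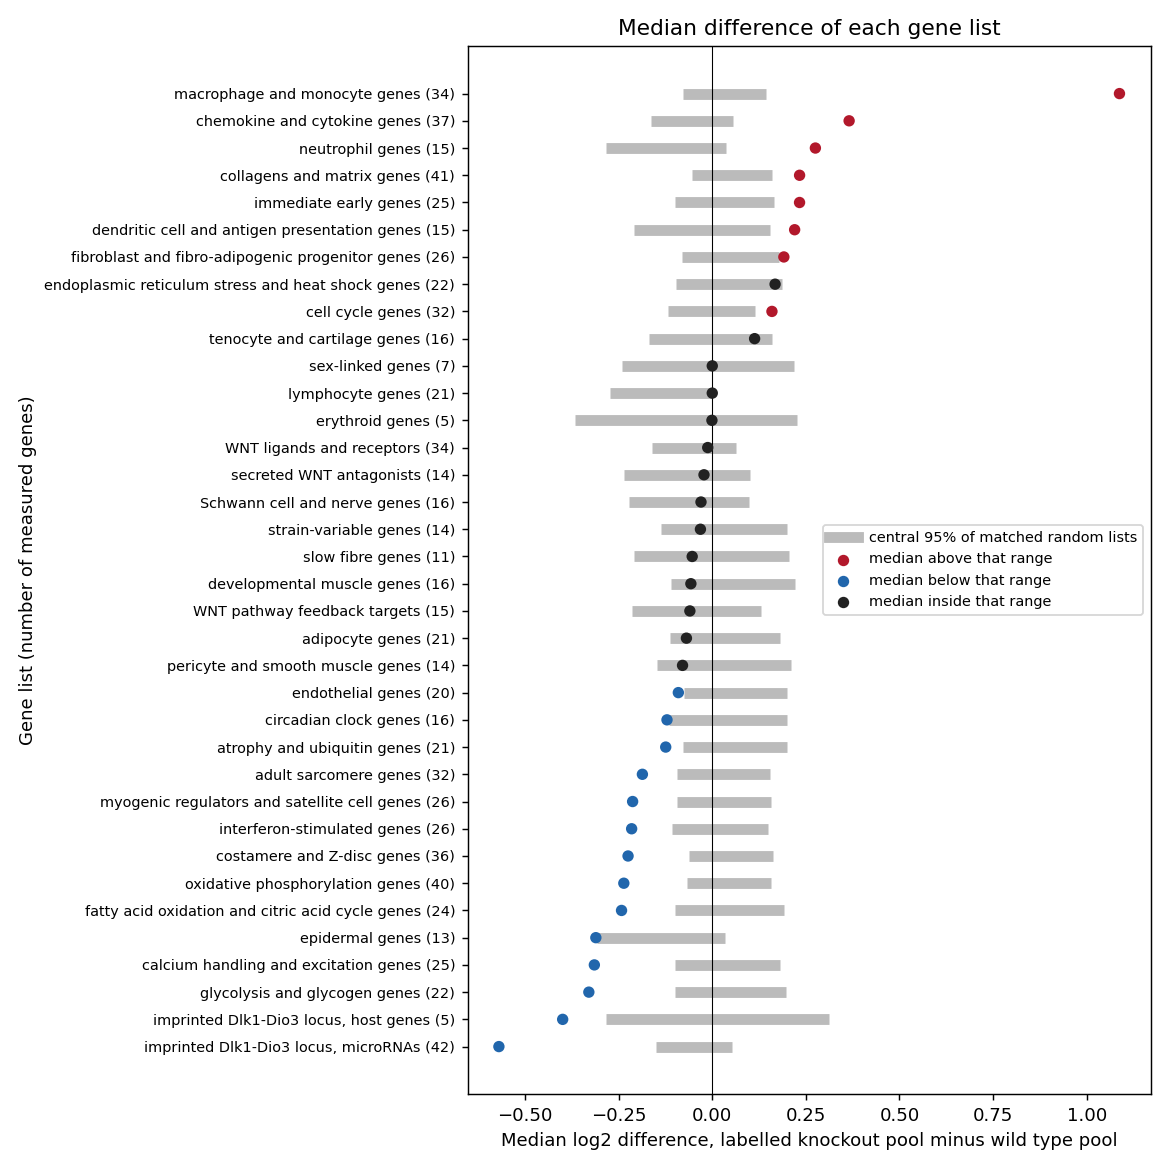
Median log2 difference (labelled knockout pool minus wild type pool, x axis) of each of 36 gene lists (y axis, number of measured genes in brackets), with grey bars for the central 95% of 10000 random lists matched on mean expression. The macrophage list lies farthest to the right at 1.09 and the microRNA genes of the Dlk1-Dio3 locus farthest to the left at -0.57, and 8 lists lie above and 14 below their grey bar.

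Genes of the muscle fibre were lower by small amounts in most of the fibre lists. Glycolysis and glycogen genes had a median of -0.33, with 5 of 22 at least 1.5-fold lower, including Fbp2 (1.80-fold), Hk2 (1.60-fold) and Phkg1 (1.58-fold). Calcium handling and excitation genes had a median of -0.31, with 2 of 24 at least 1.5-fold lower, the potassium channel Kcna7 (1.57-fold) and the chloride channel Clcn1 (1.52-fold), while Hrc differed by -0.54. In fatty acid oxidation and the citric acid cycle the median was -0.24, and Ucp3 was 1.72-fold lower. Oxidative phosphorylation genes had the same median of -0.24, with 38 of 40 lower and none past 1.5-fold. Their largest differences were those of Ndufa2 (-0.48), Cox6b1 (-0.45) and Cox6a2 (-0.41). Costamere and Z-disc genes had a median of -0.22, with 31 of 36 lower and 1 past 1.5-fold (Nmrk2, 1.92-fold), beside Sgca at -0.51 and Cmya5, which encodes myospryn, at -0.50. Adult sarcomere genes had a median of -0.19, with Mylk2 (1.60-fold) and the fast myosin gene Myh2 (1.53-fold) lower and Tpm3 at 0.58, or 0.36 with the mean of all its probe sets. These 6 lists lay at or below percentile 0.01 of their random lists. The macrophage median of 1.09 was measured in the same RNA.

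The myogenic regulator and satellite cell list had a median of -0.21 (percentile 0.00), with 2 of 24 past 1.5-fold, Chodl (1.88-fold lower) and Msc, a repressor of myogenic factors (1.56-fold lower). Developmental muscle genes, which mark young fibres, had a median of -0.06 (percentile 10.2). Among them Myh8, the neonatal myosin, was 1.54-fold lower, Runx1 was at 0.59 (0.54 with the loess trend removed, under 1.5-fold), and Myh3, the embryonic myosin, differed by -0.44. Slow fibre genes had a median of -0.05 (percentile 34.0), 5 of 11 members being higher, with Tpm3 at 0.58 (0.36 with the mean of all its probe sets), Mb, the myoglobin gene, at -0.53 and Myh7b at -0.39. Atrophy and ubiquitin genes were lower (median -0.12, mean -0.20, percentile 0.26, or 14.8 against random lists not matched on expression), with the ubiquitin ligase gene Fbxo32 1.68-fold lower, Mstn, which encodes the growth inhibitor myostatin, 1.67-fold lower, and Trim54 at -0.56. Cell cycle genes had a median of 0.16 (percentile 99.5), with none of 27 past 1.5-fold and Mcm6 (0.56), Ccne1 (0.41) and Mcm3 (0.40) largest. For these lists too, the macrophage median was 1.09 in the same RNA.

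The genes of the imprinted Dlk1-Dio3 locus on chromosome 12, which holds a large cluster of microRNA genes, were lower as lists. Of 42 measured microRNA genes, 40 were lower, and the median was -0.57, below those of all 10000 random lists. Of the 29 that were measurable, 13 were at least 1.5-fold lower and none 1.5-fold higher. Mir127 was 2.17-fold and Mir409 2.14-fold lower (Mir409 to 4.01, below the floor), besides Mir539. The list includes Mir342 and Mir345, which the reference orders before Dlk1, and without them the median was -0.59. The 5 measured host genes had a median of -0.40 (percentile 0.43), and 2 of the 4 at the floor were at least 1.5-fold lower, Dio3 (-0.13) being below it in both pools. Meg3, a long non-coding RNA also called Gtl2, was 1.91-fold (9.12 against 10.05) and Rtl1 1.61-fold lower, while Rian (-0.40) and Dlk1 (-0.28) differed by less than 1.5-fold. Probe sets with several gene symbols were left out of both lists. Among those past 2-fold, a probe set of Mirg and Mir410 differed by -1.65, and another, of Rian and AF357355, by -1.04. Probe sets at microRNA genes can pick up precursor and host RNA, and these values do not separate them from mature microRNA. Both lists were chosen for the study's interest in this locus, which may rest on these same arrays, so their direction is not independent evidence. The muscle lists above were lower, and the macrophage median was 1.09, in the same RNA.

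**Figure D3:**
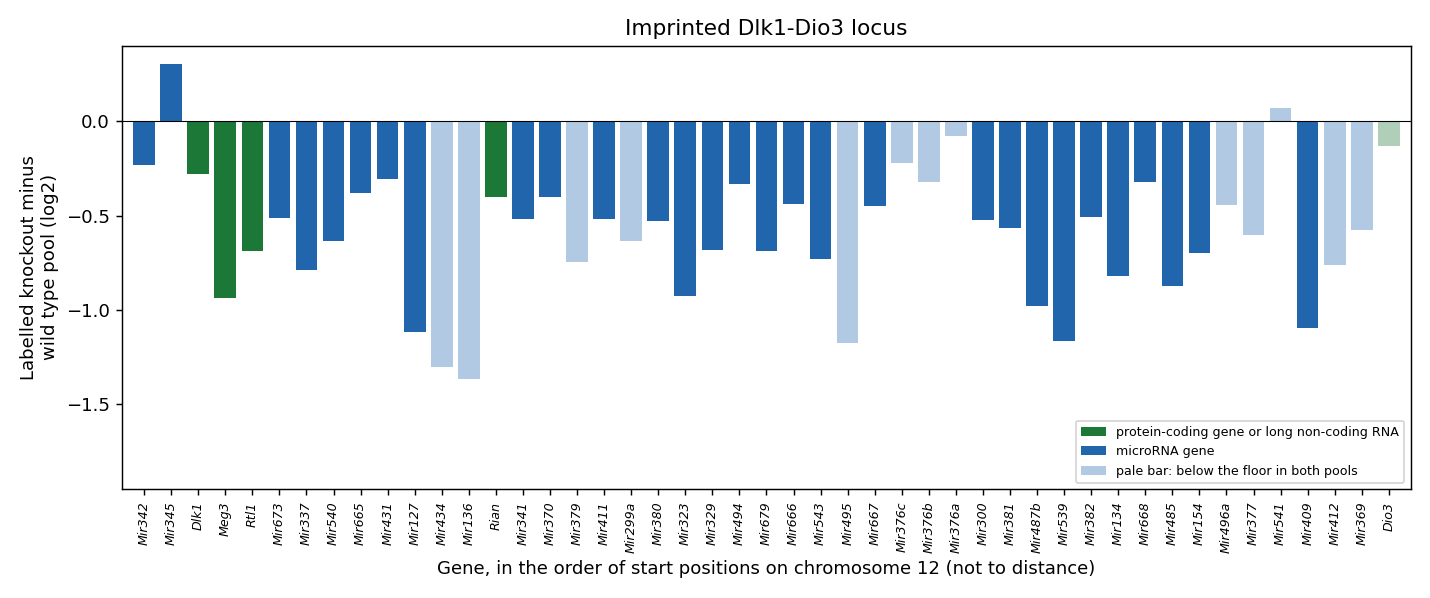
Log2 difference (labelled knockout pool minus wild type pool, y axis) of 47 genes of the Dlk1-Dio3 region in their order on chromosome 12 (x axis, not to distance), 1 bar per gene and 1 array per genotype. Of the 47, 45 are lower, and 15 genes at or above the floor are at least 1.5-fold lower. The pale bars are genes below the floor in both pools and are not in the count of 15. Some of them, such as Mir136 (-1.37) and Mir434 (-1.30), also passed 1.5-fold.

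Genes of WNT signalling went both ways. Among 8 measurable secreted antagonists, Sfrp2 (4.92-fold), Sfrp1 (2.67-fold) and, chosen after its value was seen, Dkk2 (0.61 on the log2 scale, from 3.97 below the floor) were at least 1.5-fold higher, Frzb was 2.30-fold lower, and 4 lay within 1.5-fold. The list's median was -0.02 and its mean 0.14, and it did not stand apart (percentile 69.4), its median turning to 0.094 with the loess trend removed and to 0.27 over members at the floor. Feedback targets of beta-catenin did not stand apart either (median -0.06, or 0.082 with the loess trend removed and 0.36 over members at the floor, mean 0.03, percentile 43.7), with Nkd2 1.57-fold higher, Ccn5 at 0.60 (0.53 with the loess trend removed, under 1.5-fold) and Ccnd1 at 0.50. Of the ligands and receptors (median -0.01, percentile 64.9), Fzd1 (1.74-fold) and Wnt5a (1.60-fold) were higher and Wnt6 was 1.62-fold lower, in that pool to a value of 3.90 below the floor. Sfrp2 is a gene of the study's known interest, and its direction here is not independent evidence.

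Matrix and fibroblast genes were higher as lists, in RNA where the macrophage median was 1.09. Collagens and matrix genes had a median of 0.23 and a mean of 0.36 (percentile 99.9), with 9 of 41 at least 1.5-fold higher and none lower, led by Timp1, an inhibitor of matrix proteases (3.14-fold), Tnc, the tenascin C gene (2.65-fold), and Thbs1 (2.34-fold). Fibroblast and fibro-adipogenic progenitor genes had a median of 0.19 (percentile 98.3), with 18 of 26 higher, 8 lower and 5 at least 1.5-fold higher, among them Has2, a hyaluronan synthase (2.09-fold), and Cxcl14 (1.74-fold). The tendon and cartilage list did not stand apart (median 0.11, percentile 93.0), with Fmod at 0.64 (0.58 with the loess trend removed, under 1.5-fold), Scx at -0.48 and Prg4 at 0.33.

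Endothelial genes had a median of -0.09 (percentile 1.59, or 26.6 against unmatched lists), with Vwf 1.79-fold higher, Apln at -0.40 and Sox18 at -0.34. Mural cell genes (median -0.08, percentile 12.1) held Pdgfrb, 1.57-fold higher, Lmod1 at -0.59 and Abcc9 at -0.58. Schwann cell and nerve genes had a median of -0.03, or 0.077 with the loess trend removed, and a mean of 0.02 (percentile 63.6), with Egr2 1.87-fold higher, Mbp at 0.46 and Ngfr at -0.27. Adipocyte genes had a median of -0.07 (percentile 8.96), with Plin4 2.07-fold and Slc2a4, also a fibre gene, 1.52-fold lower, and Pck1 at -0.57. Epidermal genes had a median of -0.31 (percentile 2.25, or 3.85 with the loess trend removed), but only Trp63 (-0.49) of 13 reached the floor, and with that trend removed the median was -0.16. Of 5 erythroid genes, Ermap (0.14) and Bpgm (-0.00) reached the floor, and the median was -0.00 (percentile 65.9).

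Among lists that could reflect handling or the mice used, immediate early genes were higher (median 0.23, percentile 99.9) in RNA where the macrophage median was 1.09, with 5 of 24 past 1.5-fold, including Egr2 (1.87-fold), Atf3 (1.69-fold) and Ccn2 (1.66-fold). Endoplasmic reticulum stress and heat shock genes did not stand apart (median 0.17, percentile 95.9), though they did with the loess trend removed (98.3), with the mean of all probe sets (98.6) and against unmatched lists (99.6), with 5 of 21 past 1.5-fold, among them Hspa5 (1.58-fold) and Pdia4 (0.77 on the log2 scale, but 0.51, under 1.5-fold, with the mean of all its probe sets). Circadian clock genes had a median of -0.12 and a mean of -0.04 (percentile 2.17, or 14.4 with the loess trend removed and 18.8 against unmatched lists), with Bhlhe40 1.74-fold higher, Per3 at -0.52 and Bhlhe41 at 0.50. Xist, the RNA of X inactivation in females, was 2.49-fold higher in the labelled knockout pool (8.03 against 6.72), while Y-linked Eif2s3y (-0.31) and Uty (0.06) differed by less than 1.5-fold, and the list had a median of 0.00 and a mean of 0.17 (percentile 55.6). Genes known to vary among mouse strains had a median of -0.03, or 0.025 with the loess trend removed, a mean of 0.00 (percentile 23.6) and none past 1.5-fold, with Trim30a (0.51), Ifi202b (0.34) and Entpd4 (-0.33) largest.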

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

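Some probe sets that entered no gene comparison also differed between the pools. Of 4711 probe sets at or above the floor with no gene symbol, 157 were at least 2-fold higher and 86 at least 2-fold lower in the labelled knockout pool than in the wild type pool, with log2 differences from -2.97 to 2.74. The shares, 3.33% and 1.83%, were larger than the 1.70% and 0.187% of the measurable genes. Many of these probe sets had 1 of their 2 values below the floor, such as one at 1.73 in the wild type pool and 4.42 in the labelled knockout pool. Others did not, such as one at 9.51 and 11.91. Without annotation it is not known what they measure, so the larger shares do not show that more transcripts differ. Of 861 probe sets with several gene symbols, 5 were at least 2-fold higher and 6 at least 2-fold lower, with differences from -1.65 to 1.44. The 6 hold 3 distinct pairs of values, as 4 of them are identical.

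Tests of the lower share of muscle fibres were chosen after the list medians had been seen. The other tests below were written down before their results.

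The first pattern weighed is the higher level of macrophage genes. A lower share of fibre RNA alone would raise the markers of every other cell type alike. The macrophage median exceeded that of fibroblast genes, the highest of the fibroblast, endothelial, mural and Schwann cell lists, by 0.90 on the log2 scale (combined SD of the random lists 0.087), which argues against it as the whole cause. The intensity trend found by loess ran only from -0.16 to 0.065, too small to account for it, and with it removed the macrophage median was 1.05. Other effects of the normalization were not tested. A larger number of macrophages and a different state of them stay open. As to what lies behind either, absence of MEF2A, the explanation that the design names, was not tested. It stays open beside chance differences between mice or in the muscle taken, as no replicate separates them. An unequal mix of sexes in the pools stays open too, Xist being 2.49-fold higher in the labelled knockout pool.

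The second pattern is the lower level of microRNA genes of the Dlk1-Dio3 locus. The 258 microRNA genes elsewhere were also lower (median -0.14, typical median of matched random sets -0.17), so a trend of the class may carry part of it. The locus median of -0.57 lay at percentile 0 of 10000 such sets, which argues against the class as the whole cause. Genes of the locus may be regulated together, while each set was drawn gene by gene, so the percentile measures no spread between mice or arrays. The locus median minus that of glycolysis genes, the lowest of 4 fibre lists, was -0.24 (combined SD 0.092). This does not decide on a lower share of muscle fibres, since a list median does not bound the fall of its genes. Single muscle genes fell farther than the locus median, as Atp1b4 (-1.50) and Nos1 (-1.33) did, though the medians of all 4 fibre lists did not. Imprinted genes outside the locus had a median of -0.07 at percentile 15.9 of their random lists, and thus did not share the difference as a group. A lower share of muscle fibres, alone or together with the class trend, stays open. A loss confined to the muscle cells that use the locus, and absence of MEF2A, the explanation that the design names, were not tested and stay open. So do an unequal mix of sexes in the pools and chance differences between mice or in the muscle taken, as no replicate separates them.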

How the results depend on the processing

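No paired analysis was possible because each genotype has 1 array, and no replicate could be left out. Omission of immune list members, of locus microRNA genes and of Mir342 with Mir345 was chosen after seeing the data. The count of genes at least 2-fold higher, 200, ran from 146 to 209 under other scalings, floors and probe set rules, was 176 without the immune lists' members, 760 at 1.5-fold and 40 at 3-fold. The count of lower genes, 22, was 43 with no floor, 10 with the floor at the 75th percentile, 224 at 1.5-fold and 0 at 3-fold, and otherwise ran from 17 to 30, with 19 without the locus microRNA genes. Mef2a stayed between 0.11 and 0.14. Median centring moved all differences by 0.026 and the loess trend ran from -0.16 to 0.065. No list that stood apart changed the sign of its median under the scalings, floor, mean and omission tried. With the loess trend removed, medians moved by more than the SD of the random lists to 0.094 for WNT antagonists, 0.082 for WNT feedback targets, 0.42 for neutrophil, 0.15 for lymphocyte, 0.50 for chemokine, 0.077 for Schwann cell and -0.16 for epidermal genes. Over members at or above the floor they were 0.27, 0.36, 0.94, 0.62 and 0.51 for the first 5 of these and -0.49 for epidermal genes. Means differed from medians in this way for WNT antagonists (0.14), WNT feedback targets (0.032), WNT ligands (-0.081), neutrophil (0.46), matrix (0.36), atrophy (-0.20), clock (-0.037) and sex-linked genes (0.17). Whether a list stood apart changed with loess for lymphocyte (percentile 98.1), epidermal (3.85), stress (98.3) and clock genes (14.4), with the mean of all probe sets for stress genes (98.6), and with unmatched random lists for endothelial (26.6), atrophy (14.8), stress (99.6) and clock genes (18.8). The causes were not tested. Of the named genes, Pdia4 moved by more than the local SD, to 0.51 with the mean of all its probe sets. Low signal limits the folds of genes near the floor.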

Other observations

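The gene families below were chosen after their values were seen, and the macrophage markers (median 1.09) were higher in the same RNA. Of 18 measurable subunits of the V-ATPase, the proton pump that acidifies lysosomes, 8 were at least 1.5-fold higher in the labelled knockout pool and none 1.5-fold lower, with a median of 0.44 and with Atp6v0d2 4.47-fold and Atp6ap2 2.42-fold higher. Of 12 measurable cathepsin genes, proteases of the lysosome, 9 were at least 1.5-fold higher (median 0.80), led by Ctsk (3.87-fold), Ctsl (2.62-fold) and Ctss (2.38-fold), of which Ctsk and Ctss are also in the macrophage list. All 6 measurable Clec4 genes were at least 1.5-fold higher, among them Clec4a2 (2.53-fold, from 4.07 below the floor) and Clec4a1 (2.18-fold). Of 15 measurable Asb genes, adaptors of ubiquitin ligases, 4 were at least 1.5-fold lower (median -0.28): Asb11, Asb14 (1.95-fold), Asb10 (1.89-fold) and Asb2 (1.75-fold). Asb7 was 1.59-fold higher, from a wild type value below the floor.

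The tests below were written down before their results, the osteoclast one after the 40 largest differences, and the core macrophage list after the list medians, had been seen. Acp5 and Tm4sf19 among the 12 largest differences, and Ctsk, Atp6v0d2 and Dcstamp (1.74 on the log2 scale, from 3.52 below the floor) further down the ranking, are genes of osteoclasts, and a candidate explanation is an osteoclast-like gene group raised beyond other macrophage genes. In 17 other osteoclast genes, none of them among the 40 largest differences of measurable genes, although Ccr1, below the floor in both pools, differed by 2.00, the median was 0.61 (7 of 15 measurable genes at least 1.5-fold higher, none lower). Minus the median of 12 core macrophage genes, 1.04, this gave -0.43 (combined SD 0.13). The comparison decides nothing, since the osteoclast genes with the largest differences had been left out of one list and nothing of the kind out of the other, and the explanation stays open.

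Knockout mice of mixed background can carry a strain haplotype around the targeted gene. Among the 40 measured genes that neighbour Mef2a, 31 were measurable, and of these only Asb7 was at least 1.5-fold apart (Gm10619, below the floor, differed by -0.63), against a median of 2 in 1902 windows of 40 genes elsewhere (percentile 30.1). The neighbours thus gave no sign of such an effect on expression. For the mix of sexes in the pools, the outcomes written down beforehand were Xist and Y-linked genes at least 1.5-fold apart in opposite directions, or all of them less than 1.5-fold apart. Neither was met, as Xist was 2.49-fold higher and the measurable Y-linked genes differed by less than 1.5-fold, so the mix of sexes stays open.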
